A study of Mus musculus with 4 samples.

How the data were processed

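Messenger RNA was sequenced from 4 sorted populations of mouse embryonic stem cells (ESCs), 1 library each. The cells were E14 (ES-E14TG2a), an established male mouse ESC line, grown without serum and with inhibitors of MEK and GSK3β. Per the labels, 2 clonal lines carried an integrated promoter of the Zscan4c gene: in the GFP line it drove GFP, and in the GFP-Zscan4c line it drove a fusion of GFP to Zscan4c. Each line was separated by fluorescence-activated sorting into GFP-negative cells, which the labels call pluripotent, and GFP-positive cells, which they call 2C-like because they transcribe genes of the mouse 2-cell embryo. Poly-A RNA was selected and copied with random hexamers, per the labels' protocols.

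The deposited tables give TPM, the length-scaled share of transcripts, for each library, and the submitters' processing notes name CASAVA, HISAT2 2.1.0 for alignment and StringTie 1.3.5, with the mouse build GRCm38 (mm10). The options used, the annotation release and the rule that chose the listed transcripts are not given in the sources used here. All 4 tables hold the same 58853 transcripts under 24190 gene symbols. Their TPM sum to 67.3%, 68.4%, 66.6% and 69.1% of a full TPM scale in the order GFP line GFP-negative, GFP line GFP-positive, GFP-Zscan4c line GFP-negative and GFP-Zscan4c line GFP-positive. The remaining transcripts were not analysed here, and of the 21951 protein-coding genes of GENCODE M21, which is on the same build, 13513 had a listed transcript. Of the listed transcripts, 58388 matched GENCODE M21, which supplied positions, gene types and lengths, and 465 did not. TPM keep no read counts, so the depth of each library is unknown and no counting interval can be given.

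An exact 0 could not be read as absence. Among symbols with a mean of 5 to 20 TPM in the other libraries, 35.8% were listed at 0 in the GFP-negative library of the GFP line, against 0.455%, 1.68% and 0.275% in the others in the order above. Genes at 0 are therefore called listed at 0, and values are given for each library. The total of genes 2-fold or more apart in each comparison is also given for genes above 0 in the libraries compared, a choice made after seeing the data.

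TPM were summed per symbol. Ratios are on the log2(TPM + 1) scale, which understates the change of low genes. For each pair of libraries, genes 2-fold or more apart were counted among those at 5 TPM or more in either library, without a test, since each population is 1 library. Over both lines, limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust options, two-sided, Benjamini-Hochberg adjustment) was fitted with GFP status and line as terms, over 14379 genes at 1 TPM or more in at least 2 libraries. This model has 1 residual degree of freedom per gene, and its error is the disagreement between the lines. Nothing says that the lines were sorted from separate cultures, so p-values measure only the spread between these 4 libraries. On simulated values for 14379 genes with this model's spread, the step estimated the seeded changes with a median ratio to the truth of 1.03 for log2 changes of 2 and 1.00 for log2 changes of 5. It called 0 of 100 genes of either size at an adjusted p under 0.05, and it reached an unadjusted p under 0.05 for 64 and 94 of them, so a count of 0 calls over all genes says little here.

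Before the data were examined, 29 gene lists were fixed, with 759 entries of which 96 had no row. For each list, the median log2 ratio was given as a percentile of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Transcript length was not matched. Zeros in the GFP-negative library of the GFP line rose with length, which may shift percentiles of contrasts that use it. In simulation, 6.50% of 200 unchanged lists of 30 genes fell outside the middle 95% of such lists, and all lists shifted by 0.5 lay above it. The simulated log2 ratios were independent between genes and spread less than the real ones. The standard deviation of real ratios was 1.84 in the GFP line and 1.00 in the GFP-Zscan4c line, so neither share carries over. Over the limma fit, camera was run with a preset inter-gene correlation of 0.01 and with an estimated correlation, and fry was run as well. With 1 residual degree of freedom, the residuals of any pair of genes are fully correlated or fully opposed. The estimated correlation therefore reflects only their signs and cannot decide a call. The correlation of both lines' ratios is across genes, which are not independent replicates.

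The rule for named genes was also fixed beforehand. It took, for the GFP contrast, the 15 largest increases and 12 largest decreases by the smaller of both lines' log2 ratios, 8 genes each way for the construct in GFP-positive cells, 6 each way for the difference between lines, the Zscan4 cluster, up to 4 members per list with the largest absolute mean ratio, and a fixed set of pluripotency, methylation, p53 and 2C-like genes. It gave 169 genes, of which the text gives a part; some are not reported here. Genes outside it are said to have been chosen after their values were seen. Zscan4a and several other list members had no row and were not analysed here. Copies of the Zscan4, Tcstv, Usp17l and Tdpoz families are nearly identical, so reads may have been divided among them in a way that the tables do not show, and reads of the fusion transgene can fall on Zscan4c. Strand was not stated, so overlapping genes are uncertain as well.

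Alternatives were pseudocounts of 0.1 and 5 TPM, no filter, a mean of 10 TPM or more, median-ratio scaling, quantile normalization, transcripts not summed, no line term, each library left out, other eBayes options, and a joint threshold of adjusted p and fold. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.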

Results

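The 4 libraries came from 2 reporter lines of mouse ESCs, each sorted into GFP-negative and GFP-positive cells, with 1 library per population and so no replicate error. Values are TPM per gene. The listed genes summed to between 66.6% and 69.1% of a full TPM scale, and read depth is unknown. The GFP-negative library of the GFP line stood apart: 48.4% of symbols were listed at 0 there, against 11.8% in the GFP-positive library of that line, 19.5% in the GFP-negative library of the GFP-Zscan4c line and 11.6% in its GFP-positive library. On log2(TPM + 1) values across genes, its correlation with the other libraries was 0.82 to 0.85, and theirs with each other 0.94 to 0.96.

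**Figure D1:**
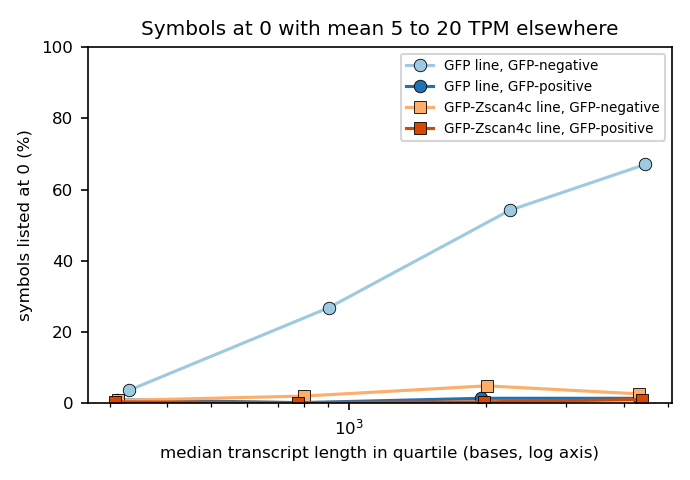
Percent of symbols listed at 0 (vertical axis) by median transcript length of each length quartile (horizontal axis, log scale), for symbols with 1 transcript and a mean of 5 to 20 TPM in the other libraries, 1 line per library. In the GFP-negative library of the GFP line (light blue) the share went from 3.66% in the shortest quartile to 67.1% in the longest.

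The first question was whether sorting on the reporter separated cells by the genes of the 2-cell embryo, and in the GFP line it did. Zscan4c, whose promoter drives the reporter, was at 9.24 TPM in GFP-negative cells and 497 TPM in GFP-positive cells. Its neighbours in the Zscan4 cluster on chromosome 7, which encode zinc finger proteins of the 2-cell stage, were higher as well: Zscan4d went from 1.504 to 108 TPM and Zscan4f from 0.174 to 170 TPM, while Zscan4b and Zscan4e were listed at 0 in GFP-negative cells and at 52.7 and 146 TPM in GFP-positive cells. Tcstv3, a 2-cell gene on chromosome 13, went from 0.884 to 44.0 TPM, and Duxf3, the Dux transcription factor gene that activates the 2-cell programme, from 0.134 to 7.72 TPM. Summed over the 5 listed Zscan4 genes, the GFP-positive value was 89.1 times the GFP-negative one.

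Core pluripotency factors stayed abundant in GFP-positive cells of the GFP line. Pou5f1 was at 1447 TPM in GFP-negative and 1075 TPM in GFP-positive cells, Sox2 at 638 and 434 TPM, and Nanog at 387 and 419 TPM. The median log2 ratio of the 30 genes of naive pluripotency was -0.28, at the 0.53 percentile of matched random lists. The glycolysis list was also low, with a median of -0.42 at the 0.02 percentile: Slc2a1, a glucose transporter, was at 512 and 198 TPM, and Pfkl, the liver phosphofructokinase, at 361 and 105 TPM. In this line 4503 of 11062 genes lay 2-fold or more apart, 3676 of them higher in GFP-positive cells. Of the 4503, 2158 were listed at 0 in 1 of the libraries, and among genes above 0 in both libraries the count was 2345, with 1539 higher. Quantile normalization moved the share of higher genes from 81.6% to 65.6% (2943 higher and 1540 lower) and the median log2 ratio of all genes from 0.19 to 0.01.

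The GFP-Zscan4c line asked the same question in cells whose GFP signal is the fusion protein, and the same families separated the populations. Zscan4c was at 4.11 TPM in GFP-negative and 366 TPM in GFP-positive cells, Zscan4d at 0.0957 and 362 TPM, Zscan4f at 0.0470 and 369 TPM, Zscan4e at 3.85 and 359 TPM and Zscan4b at 1.62 and 272 TPM. Tcstv1 and Tcstv3 were at 0.245 and 0.953 TPM in GFP-negative cells and at 48.0 and 141 TPM in GFP-positive cells, and Tmem92, a membrane protein gene of the 2C-like list, went from 0 as listed to 136 TPM. The summed Zscan4 value was 178 times higher in GFP-positive cells. Pou5f1 (1138 and 1103 TPM), Sox2 (647 and 554 TPM) and Nanog (299 and 359 TPM) again stayed abundant.

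Meiosis genes were higher in GFP-positive cells of the GFP-Zscan4c line: their median log2 ratio over 11 genes was 1.12, at the 99.95 percentile. Of them, 6 were 2-fold or more higher, 5 of these above 0 in both libraries of that line. In limma over both lines, 0 of the 11 passed when adjusted over the list alone, the smallest adjusted p being 0.082. Dazl, a germ cell RNA-binding protein gene, went from 8.71 to 31.5 TPM, and Mael, a piRNA pathway gene, from 0 as listed to 6.25 TPM. In the GFP line the meiosis median was 2.07, at the 91.83 percentile, and Dazl and Mael were listed at 0 in GFP-negative cells. Over the 3 meiosis genes above 0 in all libraries, the median in the GFP-Zscan4c line was 0.33, at the 83.85 percentile. The 8 left out were listed at 0 in the GFP-negative library of the GFP line, which has no part in that contrast. In total 1249 of 10981 genes lay 2-fold or more apart in this line, 904 of them higher. Of the 1249, 206 were listed at 0 in 1 library, and genes above 0 in both libraries numbered 1043. Median-ratio scaling moved the median log2 ratio of all genes from 0.14 to -0.01, and the share of higher genes went from 72.4% to 59.8% under quantile normalization.

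**Figure D2:**
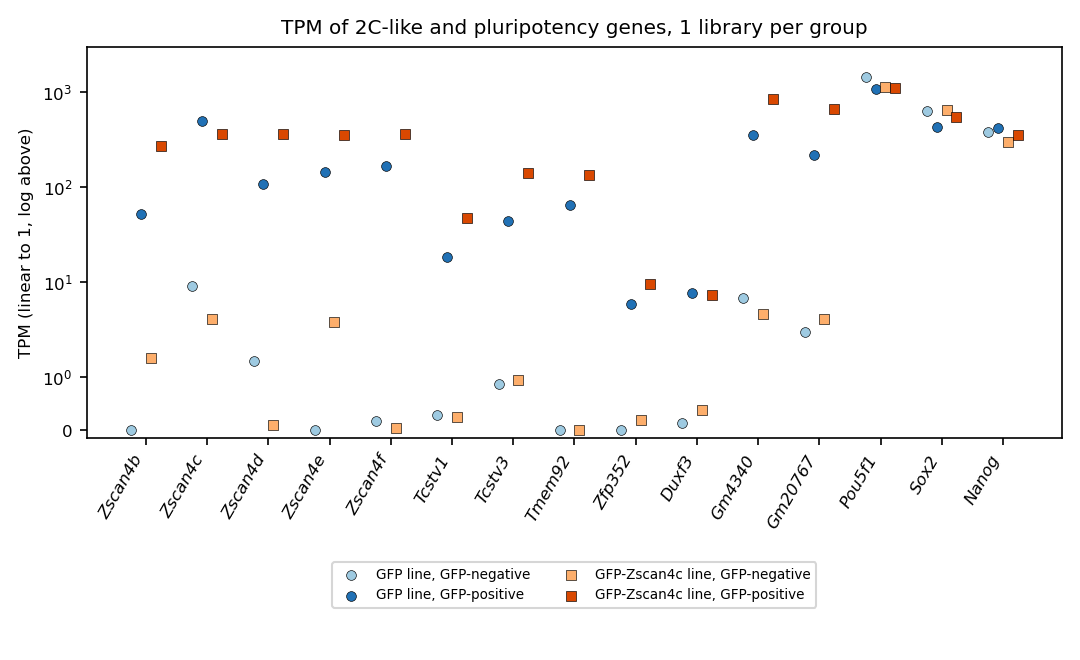
TPM (vertical axis, linear to 1 and logarithmic above) of 15 named genes (horizontal axis) in the 4 libraries, each point 1 library, blue for the GFP line and orange for the GFP-Zscan4c line, dark for GFP-positive. Zscan4 and other 2C-like genes were higher in both GFP-positive libraries, such as Zscan4c at 497 and 366 TPM, while Pou5f1 stayed between 1075 and 1447 TPM.

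Over both lines, genes of the 2-cell embryo were higher in GFP-positive cells. All 5 Zscan4 genes and 32 of 35 measured 2C-like markers were 2-fold or more higher in each line, and list medians were 5.75 and 6.71 for Zscan4 and 3.74 and 5.30 for the markers, in the GFP line and the GFP-Zscan4c line, each at the 100th percentile. These sizes depend on the pseudocount: with 0.1 TPM the Zscan4 medians were 9.04 and 7.31 and the markers' 5.82 and 6.69, and with 5 TPM they were 4.92 and 5.39, and 1.89 and 3.24. Of 49 markers fixed beforehand, 41 had a row and 35 passed the filter of 1 TPM in at least 2 libraries. A gene under 1 TPM in both GFP-negative libraries passes it only if on in both GFP-positive ones, so the filter favours genes that rise. With no filter the marker medians were 3.29 and 4.19. Of the 35 markers, 20 were listed at 0 in the GFP-negative library of the GFP line, and the medians over the 14 above 0 everywhere were 4.51 and 5.88. The markers not past 2-fold in both lines included Calcoco2 (59.1 and 94.9 TPM, then 26.6 and 28.8 TPM) and Zfp600 (30.2 and 18.2 TPM, then 27.1 and 23.5 TPM). Calcoco2 and Zfp600 were named after their values were seen.

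The 15 largest increases included clustered families of near-identical genes, among which reads are hard to divide. Neighbours on chromosome 10, Gm20765 (chr10:104185533-104188000) and Gm21312, were at 5.64 and 5.74 TPM in GFP-negative and at 357 and 357 TPM in GFP-positive cells of the GFP line. In the GFP-Zscan4c line the same genes were at 4.57 and 4.64 TPM and at 859 and 859 TPM. Gm20767, beside the Tcstv genes (chr13:120154627-120155136), went from 3.01 to 219 TPM and from 4.11 to 664 TPM. On chromosome 12, Gm8300, Gm6803 and Gm2056 were between 0 as listed and 0.991 TPM in GFP-negative libraries and between 56.3 and 157 TPM in GFP-positive ones. Gm28062 (chr1:178323074-178337728) was in the same set, at 0 as listed and 132 TPM, then 0.128 and 284 TPM, but it overlaps Hnrnpu on the same strand, which was at 207 and 168 TPM, then 169 and 47.5 TPM.

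Housekeeping genes were also in that set. Rps3a1, a ribosomal protein gene that ranked first in it, was listed at 0 in both GFP-negative libraries and at 591 and 500 TPM in the GFP-positive ones. Psmc2, a proteasome subunit gene, was at 0.348 and 0.0310 TPM against 105 and 96.6 TPM. Such values at or near 0 cannot be read as absence and may come from the assignment of reads, which was not tested for these genes. Among genes of lower rank, the naive factors Tbx3 (29.1 and 101 TPM, then 32.0 and 102 TPM) and Fbxo15 (163 and 359 TPM, then 147 and 456 TPM) were 2-fold or more higher in each line. The heat shock protein gene Hspa1a was also higher, at 5.45 and 63.4 TPM, then 2.58 and 23.8 TPM. Dppa2, which acts upstream of Dux, was at 31.8 and 85.6 TPM, then 3.02 and 66.1 TPM, and Zfp352, a 2-cell zinc finger gene, at 0 as listed and 5.93 TPM, then 0.185 and 9.57 TPM.

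Of the 12 largest decreases, 11 were processed pseudogenes, led by Gm5614 (chr9:35281518-35281835), at 73.7 and 1.11 TPM, then 67.8 and 0.538 TPM. The other was Snw1, a splicing and transcription cofactor gene, at 39.5 and 1.93 TPM, then 41.1 and 3.28 TPM. Outside that set, the splicing factor gene Srsf2 was lower (498 and 197 TPM, then 324 and 67.6 TPM), as were the ubiquitin gene Ubb (561 and 296 TPM, then 178 and 57.1 TPM) and Fn1, which encodes fibronectin (902 and 271 TPM, then 630 and 402 TPM).

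In limma's additive fit with Benjamini-Hochberg adjustment, 0 of 14379 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.397. An unadjusted p under 0.05 was reached by 972 genes, where chance gives 719. Of these, 848 were higher in GFP-positive cells, and the GFP-negative libraries hold the most zeros. The excess depended on the genes kept. The count was 568 against 519 among genes above 0 in all libraries and 809 against 540 among protein-coding genes. At a mean of 10 TPM or more it was 328 against 384, and with no filter 1128 against 1206, both below chance. Adjusted over the list alone, 5 of 5 Zscan4 genes and 31 of 35 2C-like markers passed, and over all genes 0 of either list did. The estimate for Zscan4c was a log2 ratio of 5.88 with a standard error of 0.24. Cells were sorted on its promoter, and reads of the fusion transgene can fall on it, so this estimate is not independent of the sort. Without the GFP-positive library of the GFP-Zscan4c line, 3 Zscan4 genes and 3 markers passed over the list alone. Leaving out the GFP-negative library of that line left 1 GFP-negative library, the one with 48.4% of symbols listed at 0, so its calls are not read here. Quantile normalization gave 320 genes over all genes. The smallest adjusted p in limma was then 6.5e-113 with 1 residual degree of freedom per gene, so that count says little.

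**Figure D3:**
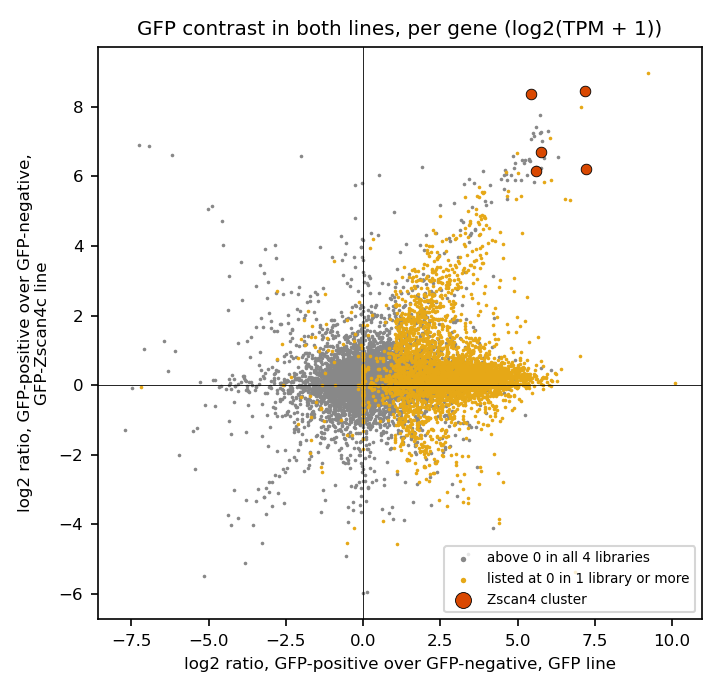
Each point is 1 of 14379 genes, with its log2 ratio of GFP-positive over GFP-negative TPM (plus 1) in the GFP line (horizontal axis) and in the GFP-Zscan4c line (vertical axis). Genes listed at 0 in 1 library or more (yellow) extend to the right, and the 5 Zscan4 genes (orange) lie in the upper right corner, above 5.4 in the GFP line.

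Beyond the 2C-like lists, medians outside the range of random lists in both lines were those of G2 and M phase, the mitochondrial genome and glycolysis. The 30 G2 and M phase genes had medians of 0.42 and 0.30, above the middle 95% of random lists in both lines, and 0.20 and 0.28 over the 24 genes above 0 in all libraries. Examples are the kinase gene Aurka (48.7 and 66.4 TPM, then 58.7 and 84.3 TPM) and Top2a, which encodes a topoisomerase of mitosis (82.4 and 242 TPM, then 228 and 335 TPM), both named after their values were seen. The 15 mitochondrially encoded genes had medians of 0.29 and 0.49, with mt-Nd6 at 311 and 499 TPM, then 287 and 959 TPM, and 13 of the 15 were higher in both lines. Glycolysis genes had medians of -0.42 and -0.07, below that range in both lines, and 14 of 22 were lower in both. In the GFP-Zscan4c line the range began at -0.06, so the glycolysis median lay only just outside it (1.64 percentile). Adjusted over the list alone, 0 members of these 3 lists passed, against 0 over all genes. None of these 3 medians changed sign under median-ratio scaling or quantile normalization, but median-ratio scaling moved G2 and M phase to 0.14 and glycolysis to -0.23 in the GFP-Zscan4c line. Camera in limma with a preset correlation did not call G2 and M phase (adjusted p = 0.302) or mitochondrially encoded genes (adjusted p = 0.180). With an estimated correlation it called none of the 3 lists (adjusted p = 0.898), but 1 residual degree of freedom makes that estimate uninformative.

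The remaining lists did not leave the range in the same direction in both lines. Heterochromatin genes had medians of 0.86 (100th percentile) and 0.19 (92.0 percentile), homologous recombination and Fanconi genes 0.74 and 0.13, p53 targets 0.23 and 0.13, telomere genes 0.31 and 0.06, end joining and mismatch repair genes 0.93 and 0.04, interferon genes 0.89 and 0.14, and S phase genes -0.18 and 0.01. Over genes above 0 in all libraries the GFP line's medians were smaller for heterochromatin (0.30), homologous recombination (0.20), p53 targets (-0.01), telomere (0.00), end joining (0.07) and interferon genes (0.10). Median-ratio scaling and quantile normalization turned the GFP-Zscan4c line's median below 0 for each of these 7 lists except heterochromatin. Members with large ratios in the GFP line included genes listed at 0 in its GFP-negative library, such as the telomere-binding gene Terf1 (0 as listed and 59.5 TPM, then 55.7 and 64.0 TPM) and Mre11a of double-strand break repair (0 as listed and 38.2 TPM, then 28.8 and 36.3 TPM). Of the p53 pathway, Trp53 was at 248 and 197 TPM, then 225 and 218 TPM, Cdkn1a, a cell cycle inhibitor gene, at 82.7 and 42.6 TPM, then 40.4 and 43.5 TPM, and Mdm2 at 36.8 and 46.2 TPM, then 64.3 and 52.0 TPM. The methylation genes Dnmt1 (81.0 and 60.7 TPM, then 57.3 and 63.3 TPM) and Uhrf1 (320 and 281 TPM, then 227 and 212 TPM) differed little, and the Dnmt1 and Cdkn1a ratios in the GFP-Zscan4c line turned below 0 under median-ratio scaling.

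For markers of other cell types and of the 2C-like state's entry, medians were 1.19 and 0.28 for 8 primitive endoderm genes, 1.02 and 0.35 for 4 mesoderm genes, 1.27 and 0.07 for 11 trophectoderm genes, 0.02 and 0.07 for 15 formative and primed genes and 0.09 and 0.20 for 31 regulators of entry into the 2C-like state, all within range in at least 1 line. Under quantile normalization the trophectoderm (-0.37 and -0.24), mesoderm (-0.06 and -0.0008) and formative (-0.58 and -0.07) medians turned below 0 in both lines. In the GFP-Zscan4c line so did the imprinted, splicing and integrated stress response medians given next. Over the 4 primitive endoderm genes above 0 in all libraries the medians were 0.04 and 0.12, since 4 of the 8 were listed at 0 in the GFP-negative library of the GFP line. Sparc of the primitive endoderm list was abundant, at 249 and 209 TPM, then 154 and 33.7 TPM. Gata4 of the same list was listed at 0 in both GFP-negative libraries and at 1.64 and 2.13 TPM in the GFP-positive ones, and Eomes of mesoderm at 0, 2.64, 0 and 3.42 TPM in the order of the lines. Over the 6 trophectoderm genes above 0 in all libraries, the medians were -0.70 and -0.29, below the range in both lines, with the trophectoderm transcription factor gene Tead4 at 27.2 and 5.39 TPM, then 21.7 and 13.5 TPM. Medians of the splicing (0.02 and 0.10), proteasome (0.01 and 0.18), imprinted (0.00 and 0.21) and integrated stress response (0.03 and 0.08) lists were also small. The proteasome median in the GFP-Zscan4c line was still above the random range (98.97 percentile), and it was 0.02 under median-ratio scaling. Adjusted over the list alone, 1 gene passed in each of 6 further lists: 2C entry regulators and naive pluripotency (Tbx3 in both), mesoderm (Eomes), fibroblast and feeder (Thy1), proteasome (Psmc2) and ribosomal proteins (Rps3a1), against 0 over all genes. Of these, Eomes, Thy1 and Rps3a1 were listed at 0 in both GFP-negative libraries, and Psmc2 was at 0.348 and 0.0310 TPM there.

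Camera with a preset correlation called 7 lists at an adjusted p under 0.05: Zscan4 (2.0e-07), 2C-like markers (1.7e-23) and meiosis (7.0e-04) higher, and glycolysis (9.5e-05), naive pluripotency (0.0369), ribosomal proteins (0.0294) and splicing factors (0.0449) lower. That preset of 0.01 treats the genes of a list as nearly independent. Near-identical copies in the 2C-like families may share reads, and the fit rests on 4 libraries. The size of these p-values therefore says little. With an estimated correlation none of the 7 passed, each with an adjusted p = 0.898. That estimate rests on 1 residual degree of freedom, so it cannot decide for or against any of these calls. Over genes above 0 in all libraries, the preset correlation no longer called meiosis (adjusted p = 0.166), naive pluripotency (0.398), ribosomal proteins (0.544) or splicing factors (0.544). It then called mitochondrially encoded genes (adjusted p = 0.00565, and 0.947 with an estimated correlation). Over all measured list genes, fry gave no list a directional adjusted p under 0.05, the smallest being 0.424. Over genes above 0 in all libraries, fry's smallest was 0.332. Even for Zscan4 the unadjusted fry p over all measured genes was 0.031, so the lack of calls by fry says little. For splicing factors the medians were above 0 in both lines while camera's direction was down, and naive pluripotency (-0.28 and 0.02) and ribosomal proteins (-0.06 and 0.10) had medians of opposite sign in the lines. In the GFP-Zscan4c line the medians of these 3 lists turned below 0 under median-ratio scaling.

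**Figure D4:**
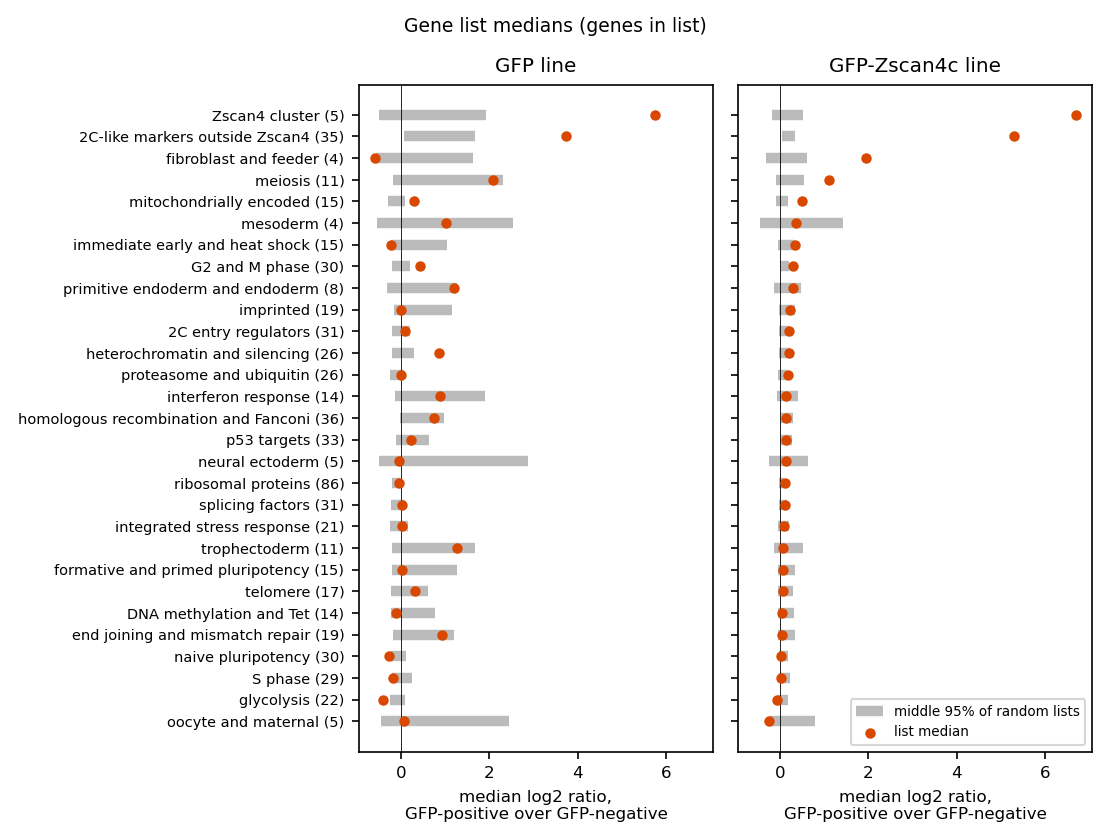
Median log2 ratio of GFP-positive over GFP-negative (horizontal axis) of each of 29 gene lists (vertical axis, with the number of genes) in both lines as orange points, over grey bars for the middle 95% of 10000 matched random lists. Zscan4 (5.75 and 6.71) and 2C-like marker lists (3.74 and 5.30) stand far outside the bars in both lines.

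Agreement between the lines across all genes was partial. Across 10245 genes, the log2 ratios of both lines had a Pearson r of 0.228 and a Spearman rho of 0.238. Genes 2-fold or more higher in both lines numbered 421, where independent lists would share 227, and genes lower in both numbered 67, where independent lists would share 12.8. The lines went opposite ways, each by 2-fold or more, at 158 genes. Without the Zscan4 and 2C-like lists, r was 0.200 over 10214 genes, and 393 genes were 2-fold or more higher in both lines, where independent lists would share 216. Over 8253 genes above 0 in the libraries compared, r was 0.260, with 198 genes higher in both lines and 67 lower in both, where independent lists would share 13.6 of the latter.

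The fusion line was next set against the GFP line within GFP-positive cells, and 2C-like genes were higher in the fusion line. Zscan4d was at 108 TPM in the GFP line and 362 TPM in the GFP-Zscan4c line, Zscan4f at 170 and 369 TPM, Zscan4e at 146 and 359 TPM and Zscan4b at 52.7 and 272 TPM. Zscan4c went the other way, at 497 and 366 TPM. Of 35 2C-like markers, 22 were 2-fold or more higher and 2 lower, with a median log2 ratio of 1.09 at the 100th percentile: Tcstv3 was at 44.0 and 141 TPM, Gm20767 at 219 and 664 TPM and Gm4340 at 355 and 855 TPM. Duxf3 did not follow, at 7.72 and 7.36 TPM.

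Genes of the integrated stress response, which amino acid shortage and unfolded protein induce, were higher as a list in the same comparison, with a median of 0.43 at the 100th percentile and 20 of 21 genes higher. Ddit3, a transcription factor gene of that response, was at 21.5 and 38.4 TPM and Nupr1 at 37.3 and 64.8 TPM. The list was also higher in GFP-negative cells, with a median of 0.24 at the 99.90 percentile. The mitochondrially encoded list had a median of 0.38 (100th percentile), the imprinted list 0.36 (99.77 percentile) and the G2 and M phase list 0.17 (99.75 percentile), while 5 oocyte genes had -1.38 (0.02 percentile), with Ooep at 30.6 and 3.21 TPM and Tle6 at 11.2 and 3.69 TPM. In total 1086 of 11126 genes were 2-fold or more apart, 635 of them higher in the fusion line, and 987 of 11027 among genes above 0 in both libraries.

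The largest ratios between the lines in GFP-positive cells included genes near 0 in both libraries of a line, in a single library, or in 1 library of each line. Of the last kind were Gm11878 (184 and 0.527 TPM in the GFP line, then 0.633 and 191 TPM) and Gm5250 (109.8 and 0.527 TPM, then 0.312 and 128 TPM), both processed pseudogenes. Higher in the fusion line were Lars2, a mitochondrial leucyl-tRNA synthetase gene listed at 0 in both GFP line libraries and at 850 and 459 TPM in the fusion line, and Eno1b, at 776 and 3.31 TPM in GFP-negative and GFP-positive cells of the GFP line, then 479 and 455 TPM. Gstp2 was listed at 147 and 0 TPM, then 101 and 96.4 TPM. Lower in the fusion line were Tep1, a telomerase-associated protein gene, at 41.9 and 54.8 TPM in the GFP line and 0 in both fusion libraries, and the noncoding Gm26825 and Gm12346, at 497 and 456 TPM in the GFP-positive library of the GFP line and listed at 0 in the other libraries. The comparison is of 1 library with 1 library, so clone, construct and sort cannot be separated in it.

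GFP-negative cells of both lines were compared to see how far the libraries differed without a GFP signal. Zscan4c was at 9.24 TPM in the GFP line and 4.11 TPM in the fusion line, and the medians of the Zscan4 (-0.17) and 2C-like marker (0.00) lists lay within the random range. Over the 3 Zscan4 genes above 0 in all libraries the median was -1.002, at the 0.74 percentile and below that range, and over all 5 it was -1.26 under quantile normalization. Dppa5a, a pluripotency gene, was at 2729 and 41.4 TPM, Vim, which encodes vimentin, at 310 and 8.16 TPM, and Ddit3 at 0.527 and 48.9 TPM. These were differences of single libraries: in GFP-positive cells of the same lines Dppa5a was at 2291 and 2280 TPM, Vim at 190 and 178 TPM and Ddit3 at 21.5 and 38.4 TPM. Immediate early and heat shock genes were lower in the fusion line, with a median of -1.05 at the 0.00 percentile, and Jun was at 6.39 and 2.19 TPM. In all 4120 of 10672 genes were 2-fold or more apart, 3214 of them higher in the fusion line. Of the 4120, 1953 were listed at 0 in 1 library, and 2167 of 8719 genes above 0 in both passed. The share of higher genes was 78.0%, and 65.3% under quantile normalization, and median-ratio scaling moved the median of all genes from 0.04 to 0.18.

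The last question was whether the GFP contrast differed between the lines. For the Zscan4 list the contrast was larger in the fusion line by a median log2 of 0.96 (99.37 percentile), and for 2C-like markers by 1.21 (100th percentile). Zscan4e went the other way, by -0.98, and with a pseudocount of 0.1 TPM the Zscan4 median was larger in the GFP line (9.04 against 7.31), where Zscan4b and Zscan4e were listed at 0 in GFP-negative cells. The heterochromatin list went the other way, by -0.46 (0.13 percentile), and by -0.24 (0.39 percentile) over the 21 genes above 0 in all libraries, since 5 were listed at 0 in the GFP-negative library of the GFP line. The random lists were not matched on transcript length, with which zeros in that library rose. Setdb1, a histone methyltransferase gene of that list, was at 2.77 and 42.1 TPM, then 37.7 and 49.5 TPM. Genes with a difference of 2-fold or more numbered 4988 of 11798, of which 3706 had the smaller ratio in the fusion line and 2448 were listed at 0 in at least 1 library, and 2540 of 9093 genes above 0 in all libraries passed. The share with the larger ratio in the fusion line was 25.7%, and 36.8% under quantile normalization, and median-ratio scaling moved the median difference of all genes from -0.06 to -0.24. Large differences were found for Atp5f1 of ATP synthase (6.58 and 139 TPM, then 117 and 5.93 TPM) and processed pseudogenes such as Gm6798 (155 and 0.0149 TPM, then 0.201 and 143 TPM). No residual degrees of freedom were left for a test of this difference, and 4120 genes were already 2-fold or more apart between the GFP-negative libraries.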

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

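The difference between lines was not tested for any result in this part, since each population is 1 library, and the tests of on and off genes, of pseudogenes, of summed copies and of cell cycle genes were chosen only after the results were seen. Results were singled out because both lines went opposite ways.

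Of the lists, 8 had medians of opposite sign in the lines, and the difference given is the median over genes of the fusion line's log2 ratio minus the GFP line's. It was 0.32 for naive pluripotency (-0.28 in the GFP line and 0.02 in the GFP-Zscan4c line), 0.17 for neural ectoderm (-0.05 and 0.12) and 1.19 for fibroblast and feeder genes (-0.59 and 1.93, over 4 genes). It was -0.80 for oocyte genes (0.07 and -0.26), -0.12 for S phase genes (-0.18 and 0.01) and 0.30 for DNA methylation and Tet genes (-0.11 and 0.05). It was 0.36 for immediate early and heat shock genes (-0.24 and 0.32) and 0.16 for ribosomal proteins (-0.06 and 0.10). Median-ratio scaling turned the GFP-Zscan4c line's median below 0 for naive pluripotency (-0.14), neural ectoderm (-0.01), S phase (-0.15), DNA methylation (-0.11) and ribosomal proteins (-0.06). Under quantile normalization both lines had the same sign for these 5 lists and for oocyte genes (-0.27 and -0.61), with ribosomal proteins at 0.08 and 0.01. Only the fibroblast and immediate early lists kept opposite signs under both scalings. In the fibroblast list, Vim was at 310 and 190 TPM in the GFP line and at 8.16 and 178 TPM in the GFP-Zscan4c line.

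Of the named genes, 10 went opposite ways by 2-fold or more in each line. The fusion line's log2 ratio minus the GFP line's was 14.17 for Gm6798, 13.80 for Gm11878, 12.80 for Gm5250, 10.09 for Gm15796, 10.05 for RP23-402P24.9, 9.29 for Gm15466 and 7.71 for Rps27. It was -12.21 for Gm25380, -8.36 for Mfap1a and -8.31 for Atp5f1. Of the 10 genes, Gm6798, Gm11878, Gm5250, Gm15796, RP23-402P24.9 and Gm15466 are processed pseudogenes.

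The first pattern is the set of common genes listed at 0 in the GFP-negative library of the GFP line, where 1622 symbols at 0 were above 5 TPM in each other library. Incomplete recovery of long transcripts fits the test set for it, among 1967 symbols with 1 transcript and a mean of 5 to 20 TPM elsewhere. Their share at 0 was 63.4 percentage points higher in the longest than in the shortest length quartile (95% bootstrap interval 58.9 to 67.9), at 67.1% against 3.66%. The quartiles were not split by gene type, and zeros also followed gene type. In the GFP line, 2137 of the 11062 genes compared were 2-fold or more higher and listed at 0 in GFP-negative cells. Of these, 2061 were protein-coding, as were 8690 of all those compared. The test therefore does not separate length from gene type. Absence of the transcripts from those cells was not excluded by the tRNA synthetases, of which 0 of 20 were at 0, but these lay above 50.6 TPM on average elsewhere, where zeros are rare. In the cell cycle lists, 8 of 59 genes were at 0, among them Kif11 and Rrm1, which dividing cells need. That count is part of the pattern itself. Absence is argued against only for such genes, by their known role and not by a measured value. Retained-intron transcripts held 5.88% of its listed TPM, against 3.47%, 3.62% and 3.60% in the others, so RNA or library quality may differ there; whether it or depth lies behind the length trend was not tested.

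The second pattern is genes near 0 in both libraries of a pair and at 10 TPM or more in the other pair. Genes on in GFP-positive cells numbered 65, of which 8 are in the Zscan4 or 2C-like lists, and genes off in GFP-positive cells numbered 4, against at most 8 in the other splits. The GFP-negative libraries are also those with the most zeros, so GFP status and failed assignment of reads cannot be told apart by either count. Reads moved between processed pseudogenes and their parent genes may account for part of the 67 genes lower in both lines, of which 46.3% were processed pseudogenes against 5.97% to 20.9% in matched random sets. A change of the parent genes themselves was not tested.

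The third pattern is the higher level of 2C-like genes in GFP-positive cells of the fusion line. A larger share of 2C-like cells in that sort, as the only cause, was taken to move these genes by 1 factor. The median absolute deviation of 26 log2 ratios was 0.416, against 0.0928 to 0.265 in matched random sets. Genes also expressed in GFP-negative cells would move less, though, and reads divided among copies could widen the spread. The random sets were matched on expression only, so this spread cannot decide for or against that cause. A different division of reads among those genes alone, as the only cause, is argued against by their summed TPM. Its log2 ratio was 0.997 against -0.30 to 0.49 in random sets. Over all listed members, the sums were 1.78 (Zscan4) and 2.08 (markers) times higher in the fusion line. Exchange of reads with other copies or copies without a row is not covered. On chromosome 12, Gm8332 was at 233 TPM in the GFP line and 2.84 TPM in the fusion line, while Gm8300, Gm6803 and Gm2056 were higher in the fusion line. A larger share and a different division acting together may also give the pattern. An effect of the fusion protein and a difference between clones are confounded with the line and untested.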

How the results depend on the processing

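The 5 lists outside the random range in both lines numbered 5 or 6 under all 9 alternatives, and the Zscan4, 2C-like, mitochondrial, glycolysis and meiosis medians kept their sign. In the GFP-Zscan4c line, naive pluripotency (-0.14 and -0.10), homologous recombination (-0.02 and -0.05) and p53 targets (-0.02 and -0.04) turned below 0 under median-ratio and quantile scaling, and p53 targets in the GFP line did at a mean of 10 TPM or above 0 (-0.01). With transcripts not summed, G2 and M phase (0.20) went inside the range and meiosis (2.01) outside it in the GFP line; above 0, meiosis went inside in the GFP-Zscan4c line (0.33). Counts are ordered as the GFP contrast in the GFP line, the same in the GFP-Zscan4c line, the fusion line against the GFP line in GFP-positive and in GFP-negative cells, and the difference of contrasts. The restrictions to genes above 0 and to protein-coding genes, and the counts over a list alone, were chosen after the data were seen.

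With no filter on low values the first 4 counts were 7023, 2402, 2105 and 6319, with more genes compared. At a mean of 10 TPM or more the 5 counts were 1655, 577, 496, 1442 and 2274, with fewer genes compared. With transcripts not summed they were 10506, 3906, 3849, 9901 and 12210. Among genes above 0, the counts were 2345 for the GFP line, 2167 between GFP-negative libraries and 2540 for the difference, since genes at 0 were left out. A pseudocount of 5 TPM gave 639 for the fusion line in GFP-positive cells, and protein-coding genes alone gave 803 for the GFP-Zscan4c line and 701 between GFP-positive libraries. The correlation between lines was 0.280 at a mean of 10 TPM, 0.111 with transcripts not summed and 0.260 among genes above 0. Without the Zscan4 and 2C-like lists it was 0.200.

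Limma's count of 0 became 3 with a pseudocount of 5 TPM, 3 at a mean of 10 TPM, 320 under quantile normalization (232 higher and 88 lower) and 21 among protein-coding genes. Leaving out each library, fitted on GFP status alone with the lone library assumed to vary like the others, gave 0 to 4204 genes, the latter without the GFP-negative library of the GFP-Zscan4c line. In that last fit the only GFP-negative library was the one with 48.4% of symbols listed at 0. Apart from those 5 settings, limma gave 0 under the other alternatives. Swapping the roles of line and GFP status also gave 0, with 523 genes at an unadjusted p under 0.05. Over the list alone, Zscan4 genes passing numbered 3 to 5 and 2C-like markers 3 to 31 with each library left out, the lowest without the GFP-positive library of the GFP-Zscan4c line, and 3 and 12 among genes above 0 in all libraries. Other causes were not tested. FPKM in place of TPM was not run, since the tables give TPM only, and unknown depth limits all statements on low genes.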

Other observations

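The genes and clusters of this part, and the test of clustering, were chosen after their values were seen. Several genes outside the 2C-like lists separated the sorted populations in both lines. Lgals4, which encodes a galectin of epithelia, was at 1.19 and 39.4 TPM in GFP-negative and GFP-positive cells of the GFP line, then 4.32 and 46.2 TPM in the GFP-Zscan4c line. P4ha2, a collagen prolyl hydroxylase gene, was at 12.3 and 67.6 TPM, then 21.2 and 116 TPM. Pmaip1, a p53 target gene that promotes apoptosis, was at 2.82 and 13.3 TPM, then 2.06 and 9.10 TPM. Nelfa, a negative elongation factor gene linked to the 2C-like state, was at 38.6 and 114 TPM, then 42.5 and 224 TPM.

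In the other direction, Hspa8, the constitutive HSP70 chaperone gene, was lower in GFP-positive cells of both lines, at 627 and 139 TPM, then 555 and 123 TPM, while its inducible relative Hspa1a was higher, at 5.45 and 63.4 TPM, then 2.58 and 23.8 TPM. The imprinted noncoding RNA Meg3 was at 350 and 218 TPM, then 508 and 279 TPM. Klf4, a naive pluripotency factor gene, went opposite ways, at 187 and 69.5 TPM, then 40.1 and 118 TPM.

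A hypothesis was that genes 4-fold or more higher in both lines lie in clusters of neighbours. Of 313 such genes with a position, 49.2% were within 1 Mb of another, against 29.1% to 42.8% in random sets of genes, which is consistent with clustering. Groups included 18 Obox4 pseudogenes on chromosome 7 (14767725 to 15444936), 14 genes around the Tcstv genes on chromosome 13, 12 around Tdpoz3 and Tdpoz4 on chromosome 3, 11 around Gm8300 on chromosome 12 and 10 genes on chromosome 10 (100330540 to 100397070). These families hold near-identical copies, so shared reads may raise neighbours together, which the test does not separate from transcription of each copy.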
